A study of Drosophila melanogaster with 6 samples.

How the data were processed

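Gene expression was measured in dissected salivary glands of *Drosophila melanogaster* prepupae on 6 Affymetrix arrays, with 1 array per RNA sample and biotin-labelled cRNA. Per the labels, animals were kept at 25 °C, given a heat shock of 30 min at 37 °C and dissected at 14 h after puparium formation. The heat shock fell at 9.5 h for w1118 animals and at 9 h for the hsGAL4 and sens animals. The groups were sens-expressing glands (3 arrays), which carry a heat-inducible GAL4 driver, and controls (3 arrays), made up of w1118 without GAL4 (2 arrays) and the hsGAL4 driver line alone (1 array).

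Per the labels, the authors computed the deposited intensity values in dChip and normalized all arrays to 1 baseline array with a median intensity of 150. The dChip version, the choice of a perfect-match or mismatch model, any filter and the array's genome build are not given in the sources used here. The deposited intensities were on a linear scale with no negative value. The table held 18952 probe sets, of which 183 were Affymetrix controls and were kept out of the tests. Of the other 18769, 13647 were paired with 1 gene symbol, 402 with several and 4720 with none in the platform annotation used here. Symbols of 13544 probe sets were looked up by gene identifier in a table of the Release 6 assembly, which served only for names and for the order of neighbouring genes. Genes of the fixed lists without a 1-gene probe set, such as *rpr* and *hid*, were not analysed here. A probe set can read more than 1 transcript, and related genes can share probes.

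Values were set on the log2(value + 16) scale, which understates the change of genes with low values. Probe sets were kept when their mean over the 6 arrays reached the 40th percentile, a value of 39.0, which left 11261 probe sets and 8373 genes in the test, with 3609 genes below it. A gene was represented by the probe set with the highest mean over the 6 arrays. limma (version 3.58.1, lmFit and eBayes with a default prior, two-sided, in R 4.3.3) compared sens with the pooled controls, and a second fit with 3 groups gave sens minus w1118, sens minus hsGAL4 and hsGAL4 minus w1118. In that fit the single hsGAL4 array was assumed to vary like the other groups. Benjamini-Hochberg adjustment ran over all kept probe sets, with a threshold of 0.05 and no fold minimum. The median log2 difference over all probe sets was -0.19 between sens and control glands, so log2 differences are given relative to the median of all probe sets of the same contrast, while adjusted p values come from the fitted values. Adding quantile normalization moved that median to 0.06, and centring each array on its median moved it to 0.03.

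Lists of genes (23, fixed with the designs, the naming rule and most alternatives before the data were examined) were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, when at least 5 members were measured. The lists covered death activators, inhibitors of apoptosis, autophagy, ecdysone response, glue and late genes, gland identity, proneural, Notch response, heat shock, secretory, immune, ribosomal, replication, vacuolar ATPase, detoxification and proteasome genes, and markers of fat body, haemocytes, muscle, nervous system, epidermis, gut and trachea. The text names *sens* and *fkh*, the 10 largest rises and falls among called genes whose 3 sens arrays lay above or below all 3 controls, and the 5 largest of each direction without a CG or CR number. It also names up to 4 called members of each list, or the 2 members with the highest mean where none was called, and the 5 largest called rises and falls of each contrast without a CG or CR number. Any other gene named was chosen after its values were seen.

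The alternatives were other pseudocounts (1 and 64), no filter or the 60th percentile, quantile normalization or median centring on top, eBayes with trend and robust, the replicate number as a block, each array left out, a fold minimum of 2, other rules for probe sets and controls, and a Welch test per probe set. Averaging sens replicates 1 and 2 as 1 sample, and leaving out sens replicate 3 with quantile normalization, were added after the data were examined. On simulated data for sens against control glands, over 8373 genes with 50 changed at each size, the main test called 4% of genes changed 2-fold, 36% at 4-fold, 54% at 8-fold and 86% at 32-fold, and 3 unchanged genes. The simulated noise was independent between arrays. It left out the near identity of sens replicates 1 and 2 and the lower reading of replicate 3, both described below. These rates therefore need not hold for the measured arrays. The number of arrays limits the precision. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.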

Results

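The data held 6 arrays of prepupal salivary glands dissected at 14 h after puparium formation, the stage shortly before these larval glands are removed. Senseless, encoded by *sens*, is a zinc-finger transcription factor known from sensory organ development, and the series asked which genes respond to it in this gland. Median values per array were 59.6 and 59.3 in w1118, 57.2 in hsGAL4, and 55.1, 56.1 and 34.8 in sens replicates 1, 2 and 3. The labels call the 3 sens samples biological replicates, yet replicates 1 and 2 were nearly identical. Over 3329 probe sets with a mean of at least 500, the SD of their log2 difference was 0.07, against 0.39 between the w1118 arrays and 0.85 between sens replicates 1 and 3. The 9 spike-in probe sets, added to the sample and thus not from the gland, had an SD of log2 difference of 0.05 between sens replicates 1 and 2 and 0.14 between the w1118 arrays. Over 12 probe sets for poly-A control transcripts, which are commonly added to RNA before labelling, the mean log2 difference was -0.061 (SD 0.05) between sens replicates 1 and 2 and 0.95 (SD 0.20) between the w1118 arrays. The gland values of replicates 1 and 2 thus differed about as little as these controls. Controls added to RNA do not cover the glands it came from, so whether replicates 1 and 2 are 1 RNA measured more than 1 time stays open. The count of called genes of each comparison is also given with both averaged as 1 sample. The p values otherwise treat them as independent. The 3' over 5' ratio of the actin control probe sets was 2.26 and 2.46 in w1118 and 1.97 in hsGAL4, and 3.27, 3.13 and 3.40 in sens replicates 1, 2 and 3. For eIF4a it was 1.51, 1.55 and 1.61 in the same controls and 2.16, 2.24 and 1.56 in sens, and for GAPDH 1.16, 1.10 and 1.19, and 1.24, 1.31 and 1.05. A second set of actin control probe sets (*Act5C*) showed no rise, with 1.497, 1.44 and 1.36 in controls and 1.41, 1.43 and 1.30 in sens, and a second GAPDH set had 5.68, 4.41 and 3.89, and 6.27, 5.37 and 4.73.

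**Figure D1:**
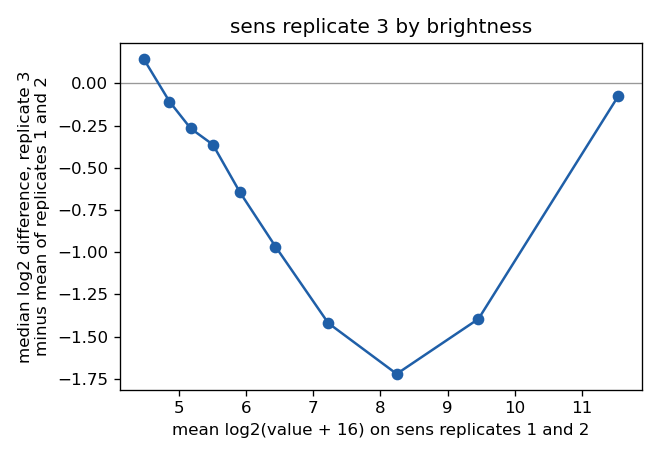
Median log2 difference of sens replicate 3 from the mean of replicates 1 and 2, plotted against the mean log2(value + 16) of these replicates, with a point for each decile of the probe sets by value. The median was -1.72 in decile 8 and -0.08 in decile 10.

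*sens* was the check on the labels. Its values were 111 and 117 in the w1118 arrays, 31.1 in hsGAL4, and 18299, 19004 and 19787 in the sens arrays. The mean rose from 86.4 ± 48.0 (SD, n = 3) to 19030 ± 744 (SD, n = 3), a log2 difference of 7.87 with an SE of 0.45 (limma adjusted p = 0.0026). The hsGAL4 value lay below the median of its array, so the size of the difference rests in part on the 16 added before taking logs, and the sens values lay near the array maxima of 19940, 20418 and 20586. An exact two-sided permutation test of the 3 arrays against 3 gave p = 0.1, the smallest it can give. With sens replicates 1 and 2 averaged, the limma adjusted p was 0.024. The gland factor *fkh*, a forkhead-family transcription factor, had values of 127, 131 and 136 in the controls and 488, 496 and 115 in sens replicates 1, 2 and 3 (limma adjusted p = 0.30, exact permutation p = 0.4). Without sens replicate 3 its adjusted p in limma was 0.0031, which treats the nearly identical replicates 1 and 2 as independent. With replicates 1 and 2 averaged and replicate 3 kept, the limma adjusted p of *fkh* was 0.52.

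**Figure D2:**
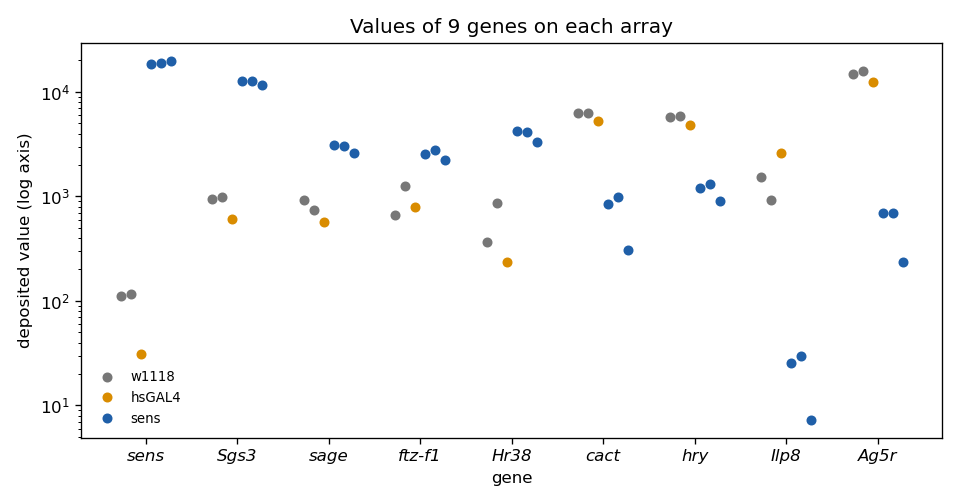
Deposited values on a log axis for 9 genes, with a point for each of the 6 arrays (w1118 grey, hsGAL4 orange, sens blue). The 3 sens arrays lay above all controls for *sens*, *Sgs3*, *sage*, *ftz-f1* and *Hr38* and below all controls for *cact*, *hry*, *Ilp8* and *Ag5r*.

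Between sens-expressing and control glands, the largest rises besides *sens* included *mRpS22*, a mitochondrial ribosomal protein gene, and *Rnf11*, a RING finger gene. *mRpS22* went from 123 ± 6.68 to 6957 ± 335 (SD, n = 3 each, log2 difference 5.85, SE 0.23), and *Rnf11* from 130 ± 102 to 6213 ± 263 (log2 difference 5.82, SE 0.48). A second *Rnf11* probe set was at 231 and 382 and did not pass (adjusted p = 0.54). The others were *CG10147* (from 0.68 to 3715, log2 difference 7.99), *CG12105* (5.51), *CG14864* (4.74), *CG13813* (4.61), *Paris* (4.45), *CG13930* (4.30) and *Boh1* (4.19). The largest falls were *CG33181* (-6.45), *CG16890* (-5.61), *Letm1* (-5.41), *Ilp8* (-5.27), *Dph4* (-4.93), *CG13050* (-4.90), *CG14569* (-4.74), *Orct* (-4.72), *CG18128* (-4.70) and *Ag5r* (-4.63). Several of these genes had values below the array median on 1 or more arrays of the lower group: *CG10147*, *CG12105*, *CG14864*, *Paris*, *CG13930* and *Boh1* in controls, and *CG33181*, *Ilp8*, *Dph4*, *CG13050*, *CG14569* and *CG18128* in sens glands. Their log2 differences and their order depend on the added 16, so they give a direction and no exact size. Part of the difference was also on the hsGAL4 array for *CG18128* (188, against 1369 and 2081 in w1118) and *CG13050* (436, against 2055 and 1586). The same held for *CG12105* (166, against 27.0 and 10.95). Against hsGAL4 alone the log2 differences of sens glands were -2.67, -3.57 and 3.89 for these genes in that order. *Letm1* encodes a mitochondrial inner membrane protein and fell from 8982 ± 1306 to 219 ± 151 (SD, n = 3 each). *Ilp8*, which encodes a relaxin-like peptide, fell from 1680 ± 835 to 20.9 ± 11.95. *Orct*, an organic cation transporter gene, fell from 2618 ± 784 to 71.5 ± 22.9, and *Ag5r*, a secreted antigen 5-related protein gene, from 14290 ± 1658 to 539 ± 261.

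In that comparison limma called 485 of 8373 genes at an adjusted p under 0.05, 170 higher and 315 lower, with 219 probe sets higher and 404 lower. In all 485 the 3 sens arrays lay above or below all 3 controls, as they did in 2961 of the tested genes, against 10% by chance for 6 independent arrays. With sens replicates 1 and 2 averaged 3185 genes were set apart, against 20% by chance. The count rested on the arrays used. Averaging sens replicates 1 and 2 left 87 genes, all among the 485. Leaving out w1118 replicate 1 or 2 gave 23 or 25, sens replicate 1 or 2 gave 82 or 103, and sens replicate 3 gave 2105 (1205 higher and 900 lower), a count that rests on the nearly identical pair against the controls. With quantile normalization on top 599 genes were higher and 680 lower, and with each array centred on its median 368 were higher and 599 lower. The excess of falls shrank under the former and largely stayed under the latter. Centring moves each array by 1 factor, which cannot take out the brightness-dependent difference of sens replicate 3 described below. Without sens replicate 3 the excess turned into one of rises. It also turned without w1118 replicate 1 (16 higher and 7 lower) or 2 (15 and 10), so it depended on the arrays used. Of the 43 named genes called here, 20 were also called with replicates 1 and 2 averaged: *sens*, *Sgs3*, *Cpr49Ac* and all the genes of the largest rises and falls except *CG12105* (adjusted p = 0.062) and *CG18128* (adjusted p = 0.10).

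Genes of the gland's own programme changed in different directions. *Sgs3*, which encodes a salivary glue protein, rose from 847 ± 204 to 12372 ± 654 (SD, n = 3 each, log2 difference 4.07, limma adjusted p = 0.0041), while the glue gene *Sgs5bis* fell (log2 difference -2.94, adjusted p = 0.040, with sens values below the array medians). The other 17 of 19 measured glue and late genes did not pass, and adjusted over the list alone 2 were higher and 3 lower. Among 9 gland identity genes 1 rose, *sage*, which encodes a bHLH factor of the gland, from 742 ± 175 to 2923 ± 257 (log2 difference 2.17), and 2 were higher adjusted over the list alone. Of 24 ecdysone response regulators 3 rose and none fell, with 3 higher and 1 lower adjusted over the list alone. They were the nuclear receptor genes *Hr38* (3.34) and *ftz-f1* (1.70), and *Cth* (1.39), which encodes cystathionine gamma-lyase. A second *ftz-f1* probe set had a log2 difference of -0.81 and did not pass, and neither did a second *Hr38* probe set at 1.84. Apart from *Sgs3* and *Cpr49Ac*, the called list members named in this and the next paragraphs lost their call with sens replicates 1 and 2 averaged.

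None of 14 death activators and effectors passed over all genes, and 3 were lower adjusted over the list alone. *Dronc*, the initiator caspase gene, had means of 6649 and 4132 in control and sens glands (adjusted p = 0.16), and *Dark*, its adaptor gene, 6384 and 3741 (adjusted p = 0.23). A second *Dark* probe set was at 792 and 184 (log2 difference -1.66) and did not pass either (limma adjusted p = 0.18). Of 4 inhibitors of apoptosis, too few for a list test, none passed over all genes or adjusted over the list alone, with *Diap2* at 4645 and 1508 and *Buffy* at 4420 and 5067. The hsGAL4 array lay below both w1118 arrays for *Dark* (4392 against 6963 and 7796) and *Diap2* (2359 against 6011 and 5565). It also did for *Buffy* (2457 against 5266 and 5535), but not for *Dronc* (7087 against 6825 and 6035). Against hsGAL4 alone, the log2 differences of sens glands were -0.05 for *Dark*, -0.49 for *Diap2*, 1.22 for *Buffy* and -0.60 for *Dronc*. Of 22 autophagy genes 1 rose, *Atg14* (log2 difference 1.45), and 2 fell, *Atg18b* (-2.13) and *Atg13* (-1.63), with the same counts adjusted over the list alone.

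Of 21 proneural and sensory organ genes only the proneural gene *ato* passed, at 36.8 ± 1.82 in control and 142 ± 13.2 in sens glands (log2 difference 1.77, which depends on the added 16 since the control values lay below the array medians), and adjusted over the list alone 1 was higher and 1 lower. Of 14 Notch response genes 1 fell, *hry* (hairy, a bHLH repressor gene), by 2.06 on the log2 scale, and 5 were lower adjusted over the list alone. Of 16 immune genes 2 rose and 3 fell, and 3 were higher and 5 lower adjusted over the list alone. The serpin gene *nec* (2.12) and the antimicrobial gene *DptB* (1.93) rose, while *CecB*, also antimicrobial, fell by 3.29 and *cact*, the inhibitor of NF-kappaB factors, by 2.98 on the log2 scale.

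The heat shock and chaperone list was the only one of 22 tested that camera called, with a median log2 difference of 0.83 over 13 genes and an adjusted p of 0.011. The call was lost with quantile normalization (adjusted p 0.052), with median centring (0.067), with the replicate block (0.43), without sens replicate 3 (0.35) and with an estimated correlation (0.88). No member passed over all genes and 2 were higher adjusted over the list alone, with *Hsp27* at 7365 and 14685 and *Hsp26* at 11027 and 16963. The other lists had camera adjusted p values of 0.085 or more, and fry called 0 lists. The median and the mean of the log2 differences had opposite signs for immune genes (0.26 and -0.23, camera upward), autophagy (0.05 and -0.11), nervous system markers (0.11 and -0.26) and proteasome genes (0.03 and -0.0030), the last 3 downward by camera. fry pointed downward and camera upward for immune, epidermis, gut, haemocyte, muscle and ribosomal genes, none of them called. Of 31 proteasome genes *Prosalpha5* fell (-1.16), also adjusted over the list alone, and of 43 detoxification genes *Cyp4e2* fell (-2.23) and 0 passed adjusted over the list alone. *Cyp4e2* was at 2891 on hsGAL4, against 8777 and 7224 in w1118, and its log2 difference against hsGAL4 alone was -1.27. None of 37 ribosomal protein, 24 secretory, 24 vacuolar ATPase or 27 replication genes passed over all genes or adjusted over the list alone. Their highest members were at 18123 and 16945 (*RpLP1*), 16264 and 17658 (*RpL41*), 7645 and 9479 (*Hsc70-3*), 4743 and 3924 (*bai*), 6769 and 8665 (*Vha16-1*), 3812 and 5353 (*Vha26*), 867 and 493 (*PCNA*) and 759 and 520 (*Dp*) in control and sens glands.

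Of 52 epidermis and cuticle genes *Edg84A* rose (log2 difference 2.45), and *Cpr49Ac* (-2.83), *Cpr31A* (-2.07) and *Edg91* (-1.31) fell, with 1 higher and 3 lower adjusted over the list alone. Of 8 fat body markers the lipase gene *bmm* fell (-2.26), and 2 were higher and 1 lower adjusted over the list alone. None of 13 haemocyte, 10 muscle, 7 nervous system, 8 gut or 11 tracheal markers passed over all genes or adjusted over the list alone. Values in control and sens glands were 3339 and 2743 for *crq*, 1156 and 1541 for *SPARC*, 439 and 414 for *bt*, 196 and 40.4 for *elav*, 201 and 106 for *nrv3*, 231 and 128 for *Jon25Bi*, 176 and 127 for *Jon66Ci*, 4267 and 3060 for *Gasp*, and 1831 and 1567 for *serp*.

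Against w1118 alone, and among genes without a CG or CR number, sens glands had the largest called rises in *sens*, *mRpS22*, *Pof* (log2 difference 5.77, SE 0.21), *Rnf11* (5.53, SE 0.50) and *laza*, a lipid phosphatase gene (5.52, SE 0.40). The largest falls among such genes were in *otu* (-5.56), *Letm1* (-5.52), *Sgs1*, a glue gene (-4.93), *Npc2e* (-4.90) and *Ilp8* (-4.90). The sens values of *otu*, *Sgs1*, *Npc2e* and *Ilp8* lay below the array medians, and so did *laza* on w1118 replicate 2, so these sizes and their order depend on the added 16. Part of these differences was also on the hsGAL4 array. Its values were 9642 for *laza* and 3478 for *Pof*, against 132 and 162 on w1118 replicate 1, and 37.0 for *Sgs1*, 70.0 for *Npc2e* and 124 for *otu*, against 918, 1579 and 1040. Against hsGAL4 the log2 differences of sens glands were -1.09, 1.47, -0.55, -0.41 and -2.62 for these genes in that order, and of these only *otu* was called. limma called 483 genes, 225 higher and 258 lower. With sens replicates 1 and 2 averaged it called 0 genes, with 1359 at an unadjusted p under 0.05. It called 0 without either w1118 array or without sens replicate 1 or 2, with 975, 1019, 1360 and 1391 at an unadjusted p under 0.05, and 4382 without sens replicate 3.

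Against the hsGAL4 driver line, which shared the driver and the heat shock time, the largest called rises among genes without a CG or CR number were these: *sens* rose by a log2 difference of 8.84 (SE 0.26), *Rnf11* by 6.39, *mRpS22* by 5.87, *Paris* by 5.43 and *Sgs3* by 4.48. The largest falls among such genes were in *Ilp8* (-6.02), the clock gene *tim* (-5.70), *PGRP-LB* (-5.53), *Dph4* (-5.35) and *Orct* (-5.20). The hsGAL4 values of *sens* and *Paris*, the sens values of *Ilp8* and *tim*, and *Dph4* on sens replicate 3 lay below the array medians, so these sizes and their order also depend on the added 16. The values of *tim* were 1973 on the single hsGAL4 array, 71.4 and 72.4 in w1118, and 13.6, 12.4 and 29.7 in sens replicates 1, 2 and 3. Those of *PGRP-LB* were 6025, 138 and 98.9, and 64.03, 80.1 and 184. limma called 118 genes, 52 higher and 66 lower. With sens replicates 1 and 2 averaged it called 0 genes, with 957 at an unadjusted p under 0.05. It called 0 without either w1118 array or without sens replicate 1 or 2, with 1003, 1009, 975 and 976 at an unadjusted p under 0.05, and 3894 without sens replicate 3. Of the 485 genes of the pooled comparison 70 were called there.

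Between the 2 kinds of control, and among genes without a CG or CR number, *laza* (log2 difference 6.64), *nAChRbeta3* (6.23), *MAN1*, which encodes an inner nuclear membrane protein (5.75), *Chi* (5.29) and *TpnC73F* (5.28) were higher in hsGAL4 than in w1118, with *laza* below the array median on w1118 replicate 2. limma called 39 genes, 37 higher and 2 lower, the latter *CG33127* and *CG15803*. With sens replicates 1 and 2 averaged it called 0 genes, with 501 at an unadjusted p under 0.05. It called 0 without either w1118 array or without sens replicate 1 or 2, with 461, 455, 504 and 510 at an unadjusted p under 0.05, and 2228 without sens replicate 3. Of these genes 27 were also higher and 2 also lower in sens than in w1118, and 0 went opposite ways, against 0.99 and 0.062 for independent lists and 0 in 100 simulations without effects. Both comparisons used the same 2 w1118 arrays, too few to split. The values for independent lists leave this sharing out, and simulations without effects call almost no genes, so neither gives the overlap that shared arrays alone would bring.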

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

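A pair of Affymetrix control probe sets, outside the comparisons above, gave signal that differed between groups; both were chosen after their values were seen. The first read above w1118, with a mean of 928 over the hsGAL4 and sens arrays, 706 in hsGAL4 and 1048, 1150 and 809 in sens replicates 1, 2 and 3, against 22.47 and 21.04 in w1118. The annotation used here does not name its target. The signal was on every array with the driver. The second, for the middle part of GAPDH, had a mean of 2076 over the sens arrays (2013, 2030 and 2185), against 942 and 888 in w1118 and 673 in hsGAL4. The 3' set of the same GAPDH series had 2623, 2633 and 2603 in sens, against 1353, 1231 and 850 in controls. Its 5' set had 2119, 2003 and 2484, against 1165, 1115 and 715. Another control probe set for the middle part of GAPDH, from a second series, had 662, 628 and 246 in sens replicates 1, 2 and 3, against 356 and 271 in w1118 and 360 in hsGAL4. The 3' and 5' sets of the second series were also lower on sens replicate 3 than on 1 and 2, so the series differed there.

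The split of the 6 arrays into sens and control gave 485 called genes, and the highest of the other splits gave 0. Only 1 of the 10 splits reached that count. Every other split had sens and control arrays on each side, so the differences between the groups entered its spread. The counts of 0 therefore do not measure chance. For gene lists 7 of the 10 splits called at least as many lists as the real one, which called 1, and the highest other called 8. With 10 splits no share under 0.05 can be reached.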

How the results depend on the processing

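Averaging sens replicates 1 and 2, and leaving out sens replicate 3 with quantile normalization, were chosen after seeing the data. The *sens* call kept its direction and side of the threshold in every setting run for it (the Welch test, the 3-group fit, the other probe set rules, the fold minimum and sens replicate 3 left out with quantile normalization were run for gene counts only), from 7.39 to 8.13 with an array left out. No called named gene turned in any of 629 values. For each of them the 3 sens arrays lay above or below all 3 controls. Leaving out or averaging arrays, other pseudocounts and other filters could thus hardly turn them, so this count is little evidence of stability. Only 9 of 42 (besides *sens*) kept their call in every setting run for them, *CG10147*, *CG13813*, *CG16890*, *CG33181*, *Dph4*, *mRpS22*, *Orct*, *Rnf11* and *Sgs3*. The cause of the changes below was not tested, except that averaging or leaving out arrays leaves fewer samples. Genes called for sens against control, w1118 and hsGAL4, and for hsGAL4 against w1118, in that order, were 485, 483, 118 and 39 as reported, 1279, 1717, 1103 and 270 with quantile normalization, 967, 1044, 476 and 95 with median centring, 784, 1042, 668 and 321 with trend and robust, and 87, 0, 0 and 0 with replicates averaged. Pseudocount 1 gave 303, 299 and 4 for the first comparisons (the 4 were *CG10147*, *mRpS22*, *Paris* and *sens*), and pseudocount 64 gave 796, 360 and 106 for the last. Without a filter sens against hsGAL4 gave 78, and at the 60th percentile 261 and, for hsGAL4 against w1118, 80. For sens against control, a Welch test per probe set with Benjamini-Hochberg adjustment gave 30 (1315 at an unadjusted p under 0.05), and leaving out sens replicate 3 with quantile normalization 1968. With an array left out the counts ran from 23 to 2105, 0 to 4382, 0 to 3894 and 0 to 2228. With the replicate block they were 980 (518 higher and 462 lower), 4001, 3027 and 1233, with 0 lists; the labels give the numbers no shared batch or day, so the samples share only a number. The correlation of replicate differences (0.0027 over probe sets) cannot test this, since sens replicates 1 and 2 are nearly identical. The block of number 3 held sens alone, so sens replicate 3 left the comparison in effect. Lists called were 1 as reported (heat shock), 5 without a filter, 2 with quantile normalization (replication and secretory genes, not heat shock), 0 with median centring, 2 with replicates averaged, 0 with an estimated correlation, 0 by fry, and 0 to 2 with an array left out. Some genes and lists that were not called turned direction. *bai* moved to 0.021 with pseudocount 1 and 0.11 averaged (-0.29 to 0.12 with an array left out), *bt* to 0.56 with the block (-0.38 to 0.51), *Jon66Ci* to 0.013 with the block (-0.89 to 0.0022), *RpLP1* to -0.18 with quantile normalization and -0.13 with the block (-0.14 to 0.27), and *serp* to 0.0021 with pseudocount 1 (-0.16 to 0.066). *nAChRbeta3* ran from -0.63 to 2.56 with an array left out. For lists camera's direction turned, with medians of 0.20 (quantile) and 0.28 (block) for immune genes (-0.040 to 0.27 with an array left out), 0.093 (pseudocount 1), 0.037 (no filter) and 0.11 (averaged) for autophagy (-0.053 to 0.15), -0.14 (averaged) for detoxification (-0.32 to -0.10), -0.11 (block) for epidermis (-0.13 to 0.37), 0.18 (averaged) for glue genes (-0.14 to 0.30), -0.017 (no filter) and -0.20 (block) for gut (-0.34 to 0.46), and -0.075 (quantile) and -0.056 (block) for ribosomal proteins (-0.067 to 0.34). Muscle markers ran from -0.093 to 0.47. Signal over background limits genes with low values, such as *CG10147* in controls.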

Other observations

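All tests in this part were chosen after the results they bear on were seen, except the share of other changed genes in the 2R stretch, which was set after the stretch was seen but before that share was. Several genes of the prepupal ecdysone sequence were also picked after their values were seen, so no test was run on them as a group. Means of the late-prepupal genes *E23*, *Strica* and *Diap2* lay lower in sens than in control glands in the relative log2 difference (-2.60, -1.88 and -1.34), with adjusted p of 0.058, 0.066 and 0.11 in limma. Those of the mid-prepupal genes *Hr3* and *Hr4* lay higher (1.90 and 1.51, adjusted p of 0.14 and 0.32), and *Hr39*, *Edg78E* and *Blimp-1* lay at 0.39, 0.65 and 0.16. Of the other late genes, *br* lay at 0.85, *Eip93F* at -0.09, *crq* at -0.12, *Dark* at -0.53 (-1.66 for a second probe set), *Dronc* at -0.49 and *Eip78C* at -1.13. None of these passed (the last 9 had adjusted p of 0.16 or more), and of the 16 genes looked at only the mid-prepupal *ftz-f1* (1.70) and *Edg84A* (2.45) were called. *br* was low on hsGAL4 alone, at 2203, against 6641 and 8632 in w1118 and 8276, 7950 and 7560 in sens. *Eip78C* was at 530 on hsGAL4, 2317 and 2699 in w1118, and 741, 798 and 346 in sens. For *Diap2* (2359), *Strica* (2908) and *E23* (2081), hsGAL4 lay below both w1118 arrays and above all 3 sens arrays.

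Sens replicate 3 read lower than replicates 1 and 2, mainly at middle brightness. Its median log2 difference from their mean was -1.72 in decile 8 of the probe sets by value and -0.08 in decile 10. That gap of 1.65, with an SD of 0.03 over 2000 resamples, argues against 1 scale factor for the whole array. More degraded RNA is argued against by the 3' over 5' ratios of 3 control genes, whose mean log2 difference was -0.23 (SD 0.29). An array-wide response that lowers probe sets below the brightest decile stays open as a hypothesis. The 5 BioB and BioC spike-in probe sets, which do not come from the gland, were lower by a median of -1.04 on the log2 scale. For 2871 gland probe sets of like value the median was -1.51. No biological explanation was tested.

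The 9 spike-in probe sets also had an SD of log2 differences of 0.05 between sens replicates 1 and 2, against 0.14 between the w1118 arrays. Mean values of the 5 dim ones were 1526 and 1405 in w1118, 707 in hsGAL4, and 564, 579 and 273 in sens replicates 1, 2 and 3, so the arrays also differed in signal that is not from the gland. Between replicate 1 of w1118 and replicate 1 of sens, the median log2 difference over all gland probe sets was only 0.03. In the deposited values a spike-in drop thus also came without a lower median of gland probe sets. The authors had normalized all arrays to 1 baseline array, so this median cannot show whether gland signal dropped before that step. The spike-ins are therefore weak support for an array-wide response on sens replicate 3.

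A set of 31 genes lay at least 3 log2 units above or below both w1118 arrays on all 4 arrays with the driver, 24 of them higher. A candidate explanation is a stretch of another chromosome background that the driver and sens lines share. Of these genes 12 lie on 2R and 19 elsewhere, and 6 of those on 2R (*Chi*, *CG33228*, *Pof*, *Tina-1*, *CG15861* and *CG3770*) lie within 108 neighbouring tested genes. The other 25 lie outside, so changes confined to genes of that stretch do not account for them. Whether genes of the stretch acted on genes elsewhere was not tested, so the stretch as the whole cause is not excluded. The stretch was also picked as the densest on 2R from these same genes. Their positions do not bear on background differences elsewhere in the genome, which these arrays cannot tell apart from the driver. Within 20 genes of each other there were 8 pairs, 5 of them on 2R, of which 4 lay in the stretch, and 3 on other arms. A permutation test of the pairs was written after the grouping had been noticed and is not used. For the genes on 2R a background stretch stays open: of the 101 other tested genes of the stretch, with *MAN1* left out since its values had been seen, 3 (2.97%) lay at least 1 log2 unit above or below both w1118 arrays on all 4 arrays with the driver, against 265 of 8209 (3.23%) elsewhere. The 95% binomial interval of that share ran from 0.62% to 8.44%, and 0.454 of 10000 random stretches were as high. The prediction written before this test counted any share at or below that elsewhere as evidence against the stretch, and by that wording it failed. Counting *MAN1*, which meets the rule, would give 4 of 102 (3.92%, interval 1.08% to 9.74%) and turn the direction, so the share decides neither way. The wording also left out the sampling spread, which the test's rule, set at the same time, required to be passed. The earlier heat shock of both driver groups cannot be told apart from the driver, since time and driver split the arrays alike; 13 heat shock genes had a median of -0.023 between hsGAL4 and w1118. An effect of GAL4 itself was not tested.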
